A study of Brassica napus with 6 samples.

How the data were processed

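Digital gene expression libraries were made from total RNA of young floral buds of 3 control and 3 amidosulfuron-treated biological replicates and sequenced from a single end on an Illumina GAIIx, per the labels and the series' design text. The labels also say that normalized cDNA was made from the RNA and do not say how; a normalization that evens out abundances would reduce the differences between high and low transcripts. Clean reads of 36 nt were aligned by the authors with Bowtie2 2.1.0, with 1 mismatch allowed, to the transcripts of an earlier Trinity assembly, and these were matched to genes of Brassica rapa FPsc 1.3, per the design text. The deposited tables give an estimated count and an RPKM value per transcript. The estimated counts were not normalized by the authors. They hold fractions such as 0.5 in all libraries. Exactly whole values, those of 0 included, make up 50.6% to 52.0% in the control libraries and 52.6% to 55.0% in the amidosulfuron libraries, where rounding to 1 decimal can make a value whole. How reads with several hits were shared out is not given in the sources used here. Transcripts of one component or of similar genes can therefore share reads, and their values are not independent. The RPKM values were normalized by the authors to transcript length and mapped reads. Dividing the deposited counts by RPKM gave, in the control libraries, whole transcript lengths in bp for 100.0% of values (tolerance 0.05 bp, shortest transcript 201 bp) and the number of mapped reads used as denominator. The kit named in the labels profiles tags, while RPKM divides by transcript length; a length factor is the same in all libraries and does not enter the comparison of groups made here.

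Each table ends at 65535 transcripts in sorted order of identifiers, so with its header it has 65536 lines, and the tabulated counts make up 30.1% to 34.1% of the RPKM denominators. The tables therefore hold part of each library, transcripts beyond the last identifier were not analysed here, and no statement about missing transcripts is made. Total counts of 1942711 to 3596321 per library set the precision: tested transcripts had a median mean count of 31.6 (quartiles 15.7 and 77.6). Reads carry no molecular identifiers, so counting intervals and floors of 3 counts cover counting error only.

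No identifier in the tables matched the RefSeq gene table given for Brassica napus (0 of 20674 Brassica rapa genes), and the files do not pair the identifiers with symbols. The 14 lists of pathway and cell type genes fixed beforehand, which included the herbicide's target enzyme and markers of other cell types, were therefore not tested. Positions in a genome are not given for the same reason.

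Estimated counts were rounded to whole numbers. Transcripts whose upper quartile of counts over the 6 libraries was under 10 were left out, as the design text describes, which left 24958 of 65535 (22115 matched, 2843 unmatched). Counts were compared with edgeR 4.0.16 in R 4.3.3 (TMM factors, glmQLFit and glmQLFTest, groups as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use TMM-scaled library sizes. The biological coefficient of variation was 30.1%. Folds of transcripts at 0 in one group were computed against 3 counts over that group. Named transcripts had to pass the threshold with no overlap between groups, a mean of at least 20 counts and a gene match; with identifiers that have no symbols, the rule names the 2 with the largest fitted rise and the 2 with the largest fitted fall, 1 per gene. Library totals were compared with a two-sided exact permutation test in scipy 1.17.1. The test, the filter, the rule for named transcripts and the alternatives were fixed before the data were examined. The rounding, the comparison of unmatched shares, the comparison of large folds by replicate and the alternatives named as such in the closing part were chosen afterwards.

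Tested on simulated counts for these 24958 transcripts with 200 changed, edgeR found 100% of 16-fold increases, 100% of 16-fold decreases, 90% of 4-fold increases and 76% of 4-fold decreases, with 11 unchanged transcripts among 194 calls. The simulated dispersion was the fitted trend and left out the differences between libraries beyond it. Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), other normalizations and filters, the thresholds of the design text, counts summed per gene or component, the replicate number as a block, and each library left out in turn. Figures were drawn with matplotlib 3.10.9.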

Results

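The study measured the transcripts of young floral buds of the rapeseed (Brassica napus) cultivar Qinyou3 after a spray with amidosulfuron. Amidosulfuron is a sulfonylurea herbicide, a class that inhibits acetolactate synthase, the first common enzyme of branched-chain amino acid synthesis. The series title describes amidosulfuron as a male gametocide, a chemical that makes plants male sterile. Plants at bolting received 0.3 mg/L amidosulfuron or water, and the buds were taken at the stage at which pollen mother cells undergo meiosis. The design has 2 groups, control and amidosulfuron, with 3 biological replicates in each. Each library was tabulated over the same 65535 assembled transcripts, of which 45722 were matched to 20674 Brassica rapa genes and 19813 had no match. The tables give these matches as gene identifiers with no gene symbol, so the results below name transcripts by identifier and describe the rest as groups. The comparison asks which transcripts of the bud differ after the spray.

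The tabulated read count per library ran from 1942711 in amidosulfuron 1 to 3596321 in control 1, and the tables hold 30.1% to 34.1% of the mapped reads behind the RPKM values. The control libraries held 2743278 ± 745224 counts and the amidosulfuron libraries 2290649 ± 503122 (SD, n = 3), a difference that did not pass a two-sided exact permutation test (p = 0.5, where 0.1 is the smallest p that 3 against 3 libraries allow). At least 1 count was found for 48834 ± 2001 transcripts in control buds and for 46621 ± 2192 in treated buds (SD, n = 3; exact permutation p = 0.3). With all libraries thinned to one total these became 46359 ± 594 and 45469 ± 649, and the difference shrank from −2213 to −889 (SD, n = 3; exact permutation p = 0.2). Transcripts with no Brassica rapa match took 7.90% ± 0.957 of the counts in the control libraries and 7.56% ± 0.163 in the amidosulfuron libraries (SD, n = 3; exact permutation p = 0.5). The 10 most abundant tabulated transcripts took between 3.61% and 4.69% of the tabulated counts in any library. The tabulated part of no library was therefore dominated by a few transcripts, and the remaining reads were not seen. A count of 0 in a single library allows a level of up to 0.89 CPM (counts on TMM-scaled library sizes) in control 1 and 1.69 in amidosulfuron 1, from 3 counts and for counting error only.

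The libraries resembled each other more within a group than between groups by about the spread of the within-group correlations. Pearson correlations of log2(CPM + 1) across all transcripts, which are not independent replicates, averaged 0.951 within groups and 0.942 between groups. The difference of 0.0089 was about the SD of the within-group correlations, 0.0085. Over the transcripts past the low-count filter the difference was 0.0274 (SD within groups 0.0214), and 0.0238 with Spearman correlations (0.0244). The first principal component held 35.8% of the variance and separated the 3 control libraries from the 3 amidosulfuron libraries. The second held 29.3% and set control 3 and amidosulfuron 2 apart from the other 4 libraries. These libraries of different groups correlated at 0.961, above the correlation of control 3 with either other control (0.938 and 0.949) and of amidosulfuron 2 with either other treated library (0.956 and 0.950).

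**Figure D1:**
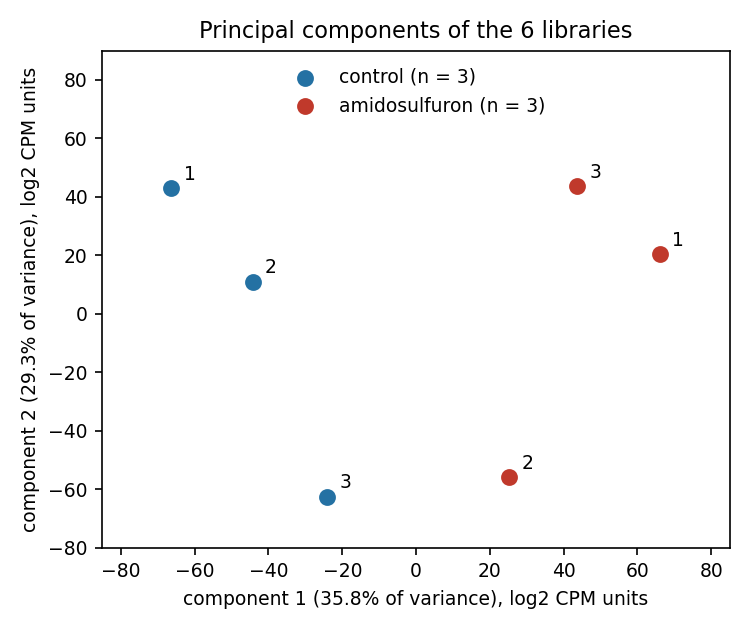
Principal components of the log2 CPM of transcripts past the low-count filter, one point per library, numbered by replicate, with component 1 on the x axis and component 2 on the y axis. Control and amidosulfuron libraries lie on opposite sides along component 1, and control 3 and amidosulfuron 2 lie together at −62.5 and −55.8 on component 2.

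Buds sprayed with amidosulfuron gained a small set of transcripts that were low in control buds. Of 24958 transcripts tested, 40 were higher and 8 were lower after amidosulfuron at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). The 40 that rose had a median level of 1.12 CPM in control buds and 72.8 CPM in treated buds, a median change of 68.7-fold (ratio of group mean CPM) with the 5 that rounded to 0 in every control library set at 3 counts over that group. Each rose at least 8.39-fold, 32 rose more than 16-fold, 18 had a control mean under 1 CPM and 31 one under 5 CPM. Together they amounted to 102 CPM ± 8.69 in the control libraries and 4567 CPM ± 2620 in the amidosulfuron libraries (SD, n = 3). The 8 that fell went from 250 CPM ± 94.1 in all to 23.7 CPM ± 4.69 (SD, n = 3), with changes between 4.37-fold and 180-fold. All 40 and all 8 showed no overlap between the 3 treated and the 3 control values, a criterion that chance gives for 10% of transcripts and that 15.4% of all tested transcripts met, 1929 upwards and 1914 downwards. The count of calls changed when single libraries were left out. Such a fit also has fewer libraries and so less power, and these effects were not told apart. The numbers of transcripts that rose and fell were 5 and 12 without control 1, 0 and 0 without control 2, 11 and 8 without control 3, 20 and 1 without amidosulfuron 1, 224 and 16 without amidosulfuron 2, and 9 and 1 without amidosulfuron 3. Without control 2, edgeR still gave 2406 transcripts at an unadjusted p under 0.05, and DESeq2 called 123 higher and 76 lower. With all 6 libraries DESeq2 called 185 higher and 116 lower, and limma-voom called 0 and 0 with 2370 transcripts at an unadjusted p under 0.05. On a split of the libraries that mixes the groups (control 1, control 2 and amidosulfuron 3 against the rest) DESeq2 called 279 transcripts, against 301 for the real groups, and edgeR called 0. That split was the highest of those that mix the groups, and DESeq2 called 0 to 61 on the others. With no filter on low counts edgeR called 246 higher and 269 lower, which turned the balance of the directions.

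**Figure D2:**
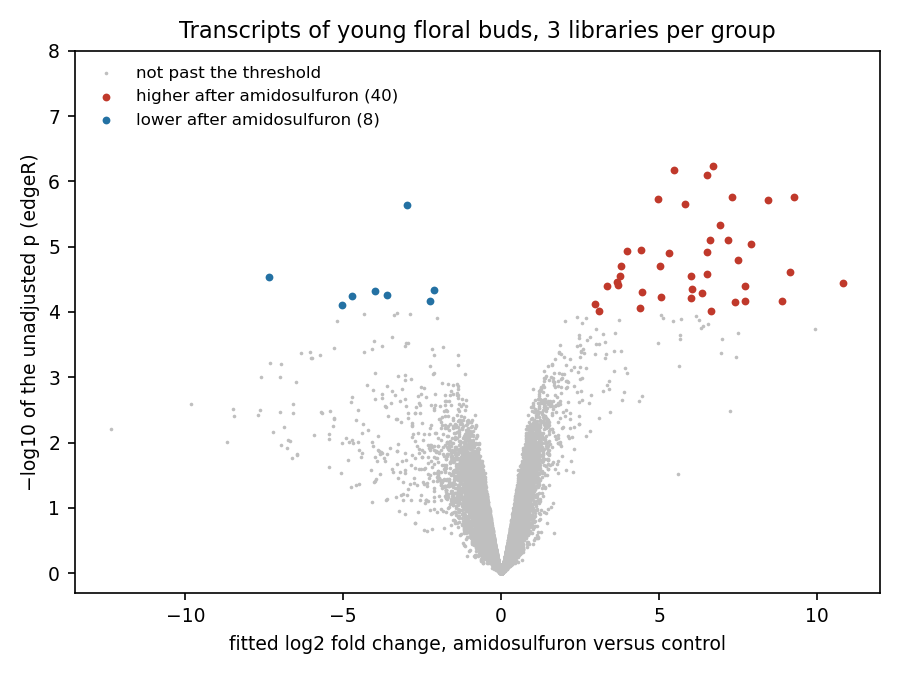
Fitted log2 fold change of each of the 24958 tested transcripts (x axis, amidosulfuron versus control) against the negative log10 of its unadjusted edgeR p (y axis). The 40 transcripts that rose are red, the 8 that fell are blue and all others are grey; fitted folds of transcripts at 0 in one group depend on the prior count of the fit.

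Of the transcripts that rose, the rule for named transcripts selected comp3559_c0_seq1, matched to Brara.G01957, and comp36646_c0_seq1, matched to Brara.I01855. The transcript comp3559_c0_seq1, 792 bp long, had no count in any control library and 318, 121 and 118 counts in the 3 amidosulfuron libraries. Its mean level in treated buds was 93.8 CPM ± 74.4 (SD, n = 3; edgeR adjusted p = 0.033). Its 557 treated counts, pooled over the summed library sizes of the group, were at least 224-fold higher than the 3 counts that a control total of 0 allows (0.376 CPM). The other tested transcript of Brara.G01957 was also among the 40, and with the transcripts of the gene summed the fitted log2 fold was 6.76 in place of 10.83 (edgeR adjusted p = 0.00862). The transcript comp36646_c0_seq1, 278 bp long, rounded to 0 counts in every control library and had 84, 48 and 46 counts in the amidosulfuron libraries. It reached a mean of 29.2 CPM ± 16.1 (SD, n = 3, edgeR adjusted p = 0.029), and its 178 pooled counts were 71.6-fold higher than the same control limit. Its control values held fractions of counts that rounding removed. The limit is that of a control total of 0, so 71.6 is not a lower bound for this transcript. With unrounded counts the fitted log2 fold of comp36646_c0_seq1 was 7.99 in place of 9.14 (edgeR), and under limma-voom it was 7.10.

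Of the transcripts that fell, the rule selected comp50189_c0_seq2, matched to Brara.F03027, and comp54689_c1_seq4, matched to Brara.D00030. The transcript comp50189_c0_seq2, 721 bp long, fell from 82.6 CPM ± 66.7 to 0.458 CPM ± 0.524 (SD, n = 3; edgeR adjusted p = 0.029). Its 3 counts in all treated libraries against 595 in the controls gave a ratio of 164 on pooled counts (180 from the mean CPM), with an exact 95% interval from 56.0 to 799 that covers counting error only. Control 2 held 354 of the 595 counts, at 155 CPM against 23.7 in control 1 and 68.9 in control 3, and the fitted log2 fold went from −7.35 to −6.51 without it. The transcript comp54689_c1_seq4, 418 bp long, fell from 25.7 CPM ± 11.6 to 0.916 CPM ± 1.05 (SD, n = 3; edgeR adjusted p = 0.038). Of the transcripts matched to Brara.D00030, 4 were tested. When the counts of all tabulated transcripts matched to this gene were summed, the fitted log2 fold was −2.76 and no longer passed the threshold (edgeR adjusted p = 0.286). With the transcripts of its assembly component summed it did not pass either (edgeR log2 fold −0.99, adjusted p = 0.266).

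The edgeR calls of these 4 transcripts were lost in several fits without 1 library. DESeq2 without any one library kept each call for which it gave an adjusted p (highest 0.00102). A fit with fewer libraries has less power, so a lost call does not by itself show dependence on the library left out. Both that rose missed the threshold without control 1, control 2, control 3 or amidosulfuron 3 (highest edgeR adjusted p 0.135 for comp3559_c0_seq1 and 0.13 for comp36646_c0_seq1). The call of comp50189_c0_seq2 ended without control 2, control 3, amidosulfuron 1 or amidosulfuron 3 (highest adjusted p 0.105). That of comp54689_c1_seq4 ended without control 2, control 3 or any one of the 3 amidosulfuron libraries (highest adjusted p 0.142). The fitted log2 folds kept their sign without any one library, which could hardly change because the rule required no overlap between groups. They lay between 10.03 and 11.13 for comp3559_c0_seq1 (10.83 with all libraries, lowest without amidosulfuron 1) and between 8.68 and 9.38 for comp36646_c0_seq1 (9.14). They lay between −8.30 and −6.51 for comp50189_c0_seq2 (−7.35) and between −5.76 and −4.29 for comp54689_c1_seq4 (−4.73), with the largest fall of both without amidosulfuron 3. Fitted folds of transcripts at 0 depend on the prior count of the fit. Over all alternatives the adjusted p ran from 1.39e-10 to 0.392 for comp3559_c0_seq1, from 7.86e-09 to 0.374 for comp36646_c0_seq1, from 4.63e-13 to 0.494 for comp50189_c0_seq2 and from 5.5e-08 to 0.428 for comp54689_c1_seq4 (DESeq2, edgeR and limma-voom).

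**Figure D3:**
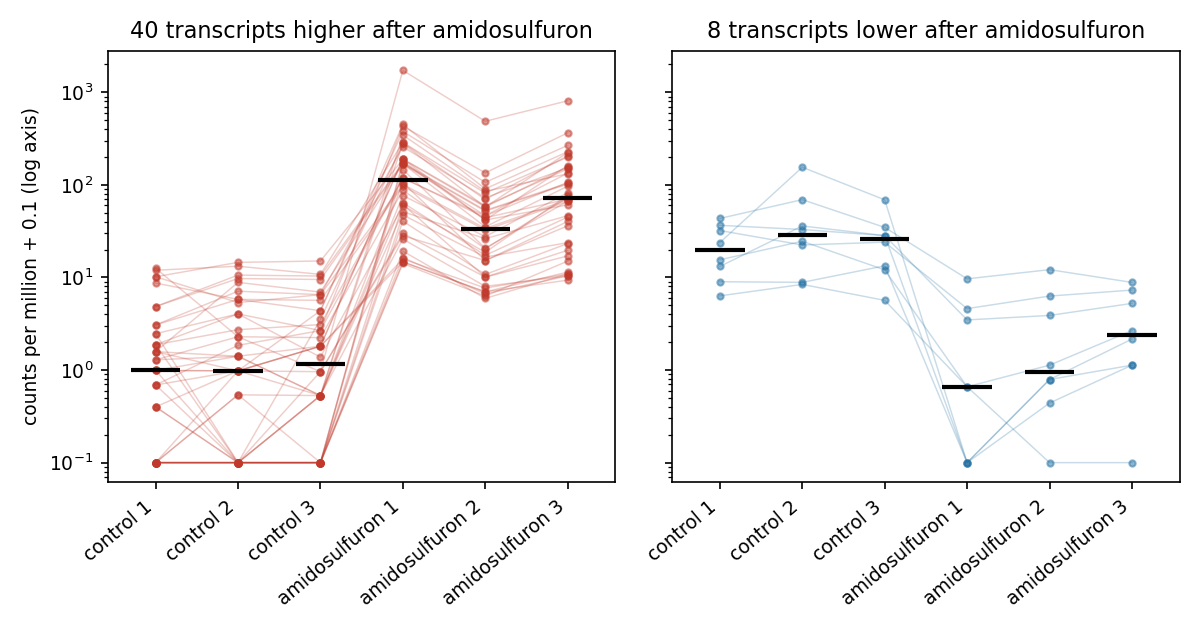
Level of each of the 40 transcripts that rose (left) and the 8 that fell (right) in the 6 libraries, as CPM + 0.1 on a log axis; each thin line joins the values of 1 transcript and each black bar is the median of a library. Summed over the 40, the amidosulfuron libraries reached 7228, 1984 and 4489 CPM and the controls 91.7 to 107 CPM.

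Some of the 40 transcripts that rose shared a Brassica rapa match. The 40 belonged to 34 assembly components. Of them, 35 matched 23 Brassica rapa genes, 7 of which contributed 19 transcripts, and 5 had no match. Sharing was also common among all tested transcripts, of which 22115 matched 12039 genes, and a concentration in few genes was not tested. Whether transcripts with the same match come from the same rapeseed gene is not given in the sources used here. The 8 that fell came from 8 components, with 7 matched to 7 genes and 1 without a match. The share of unmatched transcripts among the 48 did not differ detectably from that among the other tested transcripts (6 transcripts, odds ratio 1.11, Fisher's exact test, p = 0.82). With the counts of all transcripts of a gene summed, 16 of 13040 genes rose and 3 fell at an adjusted p under 0.05 (edgeR). Of these, 15 and 2 were already represented among the transcripts that rose and fell.

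Large decreases were more numerous than large increases, in comparisons chosen after the calls were seen. The control replicates of the decreases were less even than the treated replicates of the increases. A fitted change of at least 4-fold was reached upwards by 140 transcripts and downwards by 266, of which 40 and 8 passed the adjusted threshold. In the group with the higher level, the ratio of the highest to the lowest replicate had a median of 3.5 (quartiles 2.9 and 4.8) for the 140 and of 7.5 (quartiles 4.3 and 22.4) for the 266, with replicates under 3 counts set at 3 counts of their library. The 140 were thus measured in treated libraries and the 266 in control libraries. Past the filter, Pearson correlations ran from 0.8837 to 0.9124 among controls and from 0.8995 to 0.948 among treated libraries. A general difference in evenness between the groups was not taken out. Large decreases also outnumbered large increases in each of the 20 alternatives fitted to the same transcripts. The highest treated value was that of amidosulfuron 1 for 123 of the 140, of amidosulfuron 3 for 16 and of amidosulfuron 2 for 1. The highest control value of the 266 was spread over control 1 (94), control 2 (82) and control 3 (90).

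The design text calls a transcript changed at an unadjusted p of at most 0.05 and an absolute log2 fold change of at least 1. At these thresholds 618 transcripts were higher and 749 were lower in the amidosulfuron group (edgeR), 1367 in all. Among the splits that mix the groups, the highest (control 1, control 2 and amidosulfuron 3 against the rest) gave 1359. The others gave 155 to 1048. The balance between the directions was not stable at these thresholds. With the RPKM denominators as library sizes they gave 471 higher and 988 lower. It turned under limma-voom (570 higher, 426 lower), without control 1 (572 and 476 with edgeR, 470 and 330 with DESeq2) and without amidosulfuron 2 (1024 and 881 with edgeR, 848 and 719 with DESeq2).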

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

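The tests with RPKM denominators, with unrounded counts, with 2 libraries left out together, on whole counts only and summed per component, DESeq2 with a library left out, and all alternatives for the thresholds of the design text were chosen after the data were examined. Summing and the restriction to whole counts left aside, 22 alternatives were run on transcripts. In each, all 40 transcripts that rose and all 8 that fell kept their direction and an unadjusted p under 0.05. They were selected on the same libraries and showed no overlap between groups, so leaving out a library could hardly reverse a direction. The number of calls did not hold. For transcripts that rose and fell (40 and 8), DESeq2 called 185 and 116, including all 48, and limma-voom called 0 and 0 (smallest adjusted p 0.065, with 2370 transcripts at an unadjusted p under 0.05). Calls numbered 246 and 269 with no filter on low counts, 49 and 15 with filterByExpr, 51 and 13 with library totals in place of TMM, 68 and 18 with the RPKM denominators as library sizes, 16 and 3 with transcripts of one gene summed, 25 and 4 among the 3601 transcripts with whole counts in the controls, and 618 and 749 at the thresholds of the design text. The RPKM denominators moved the median log2 fold of all transcripts from −0.02 to −0.12. Leaving out one library gave 0 (control 2) to 224 (amidosulfuron 2) rises and 0 to 16 falls; with DESeq2 it gave 110 and 65, 123 and 76, 156 and 156 (controls 1 to 3), 73 and 49, 524 and 141, and 97 and 68 (amidosulfuron 1 to 3). Leaving out control 3 and amidosulfuron 2 together gave 164 and 66. The replicate number as a block gave 75 rises and 44 falls, of which 39 and 6 were among the 40 and 8. The labels do not say whether equal numbers pair the libraries. Deviations from the group means correlated at 0.14, −0.12 and −0.40 for replicates 1, 2 and 3, and control 3 correlated best with amidosulfuron 2 (0.36). So few libraries per group cannot decide whether the numbers pair them. The 1367 transcripts at the thresholds of the design text became 3573 with no filter, 690 summed per gene, 909 summed per component, 319 with whole counts in the controls and 2550 without control 3 and amidosulfuron 2; leaving out one library gave 1030 to 2041 with edgeR and 800 (control 1), 806 (amidosulfuron 1) to 1567 with DESeq2. More transcripts rose than fell there under limma-voom, and without control 1 or amidosulfuron 2 with edgeR and DESeq2. The excess of within-group over between-group correlation was 0.0089 over all transcripts, 0.0274 (Pearson) and 0.0238 (Spearman) past the filter. The difference in detected transcripts (−2213) was −2390 at 10 counts and −889 after thinning. The 4 named transcripts under the alternatives that gave an adjusted p made 96 results, each 1 transcript under 1 alternative. None reversed the direction, which the required lack of overlap between groups made unlikely beforehand. In 25 of the 96 the adjusted threshold was missed, with adjusted p-values up to 0.494 (limma-voom). The cause of these differences was not tested, except that summing and whole counts test fewer features. Alternatives for gene lists were not run because no list could be matched, and those for normalized values did not apply to counts.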

Other observations

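All tests in this part except those of transcript length, depth, shared reads and isoform directions were chosen after the result was seen. Treated buds differed among themselves in how strongly the rising transcripts rose. Among transcripts called without amidosulfuron 2, 1 per component, 178 rose, and in amidosulfuron 2 they stood at a median of 0.24 of the way from the control mean to the mean of the other treated libraries (95% bootstrap interval 0.22 to 0.26); 170 stood under 0.5. The 15 that fell stood at 0.88 of the way (0.49 to 1.00). Chosen in the same way without amidosulfuron 1, 19 risen transcripts stood at 2.15 (2.04 to 2.68) in that library, and 8 chosen without amidosulfuron 3 stood at 1.25 (1.01 to 1.40) in that one. Transcripts are not independent replicates, and each position describes 1 library. Choosing transcripts as high in the other treated libraries favours positions under 1, by an amount that was not measured. The positions of amidosulfuron 1 and amidosulfuron 3 are relative to a mean that includes amidosulfuron 2.

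The weaker rise in amidosulfuron 2 was set against 3 technical explanations. Mixing with RNA of unsprayed buds at the mean level of the controls would bring risen and fallen transcripts equally far towards that level. The fallen stood 0.64 further from it (95% bootstrap interval 0.28 to 0.76), on 15 fallen transcripts. Mixing with RNA unlike that mean, such as that of a single control, was not tested. Scaling of the library would shift all transcripts alike, but the risen ones lay −1.24 on the log2 scale (−1.29 to −1.16) relative to all others, a difference that no scaling changes. The choice of the risen ones also favours a negative value here, by an amount that was not measured. A label exchanged with a control would leave the risen transcripts at the control level, but 97.2% of them exceeded the highest control in amidosulfuron 2. A difference between plants in exposure to the spray, in time since the spray or in bud stage may account for the pattern and was not tested, since the labels give 1 dose and 1 stage.

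Control 3 and amidosulfuron 2 resembled each other across all transcripts. The mean deviation of this pair from the other 4 libraries hardly followed transcript length (Spearman rho 0.062 across 24958 transcripts), which argues against a length bias as the source. After thinning of all libraries to one total, the pair still correlated at 0.953, above the best correlation of either with its own group, by 0.0032 in place of 0.0058; the bound set beforehand lay above the margin before thinning, so it could not be met, and depth may explain part of the resemblance. A shared processing day or a shared bud stage remains open, and the labels name neither. Leaving out both libraries gave 164 rises and 66 falls in place of 40 and 8, but leaving out amidosulfuron 2 alone gave 224 and 16 and leaving out control 3 alone gave 11 and 8, so among these fits the rises were most numerous without amidosulfuron 2 alone and the falls with both left out.

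Genes with consecutive Brassica rapa numbers occurred more often among rising genes than in random sets. At the thresholds of the design text, the 370 genes with a higher transcript held 10 such pairs, against a mean of 3.66 in 10000 random sets of tested genes (permutation p = 0.0047), and the 487 with a lower transcript held 9 against 6.32 (permutation p = 0.19); the difference between the directions was not tested. The 23 genes of the 35 matched transcripts that rose held 2 pairs, against a mean of 0.01 in random sets (permutation p = 0.0001, the smallest that 10000 sets can give). Reads shared between similar transcripts could produce such pairs. Among genes with whole counts in every library the 65 higher genes held 0 pairs, where chance gives 0.13, so too few genes were left to decide. Whether consecutive numbers mean neighbouring genes is not given in the sources used here.

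Transcripts of one assembly component did not move in opposite directions. Of 4792 components with several tested transcripts, 0 held both a higher and a lower transcript at the thresholds of the design text, where 2000 shuffles of the directions gave 12 to 29 (95% range; two-sided permutation p = 0.001, the smallest that these shuffles can give). Transcripts changed in the same direction in 164 components, where shuffles gave a mean of 21.5. A candidate explanation is that reads shared between isoforms tie their counts together, which was not tested; the 0 opposite components do not show that isoform use was unaltered.

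With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. At the adjusted threshold 1 split, the real one, gave 48 transcripts and the highest of the others gave 0 (edgeR). At the thresholds of the design text the real groups gave 1367 and the highest other split gave 1359. With DESeq2 at the adjusted threshold the real groups gave 301 and that same split, control 1, control 2 and amidosulfuron 3 against the rest, gave 279. The other splits that mix the groups gave 0 to 61. Each side of that split keeps most libraries of one group, so the treatment is still partly contrasted. The cause of the 279 calls and their overlap with the 301 were not tested.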
